A study of Mus musculus with 4 samples.

How the data were processed

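RNA sequencing had been done on monocytes sorted by flow cytometry from the bone marrow of wild-type C57BL/6 mice, with 2 libraries from mice aged 18 months and 2 from mice aged 3 months. The labels tag all libraries with atherosclerosis as the disease and do not say whether the donors had plaques. Per the labels' protocols, messenger RNA was selected with oligo-dT beads, fragmented and turned into strand-specific libraries by dUTP marking. The deposited values are raw counts per gene symbol, 1 table per library, with no normalization applied by the authors. The submitters' processing notes name cutadapt, STAR 2.5.3, HTSeq, DESeq2 and the mm10 build, without stating what each did. The annotation behind the counts and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands, such as mt-Nd5 and mt-Nd6, may share reads. Oligo-dT selection also leaves out most transcripts without a poly(A) tail, which matters for replication-dependent histone genes.

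Each table held 31017 gene symbols in the same order and no rows for unassigned reads. Of these symbols, 30416 matched exactly 1 gene of that name in GENCODE M21, which uses the same mouse assembly (GRCm38, also called mm10) and gave gene identifiers and coordinates. The other symbols entered the tests without coordinates. Library totals were 24918091 and 21837261 counts for aged replicates 1 and 2, and 34278754 and 20159129 for young replicates 1 and 2. A count of 0 is compatible with up to 3 counts, which is 0.120 and 0.137 CPM (counts scaled to the library size) in the aged libraries and 0.0875 and 0.149 CPM in the young ones. Intervals and floors cover counting error only, since reads from amplified libraries are not independent molecules. Members of near-identical families are uncertain where reads could be split, which holds for immunoglobulin V genes, histone genes, haemoglobin genes, H2 genes, Hspa1a with Hspa1b, and the ribosomal RNA-like Gm42418, Gm26917 and Lars2.

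The groups were taken from the labels, and the only comparison the design gives is aged against young. Genes were kept by filterByExpr with the age group (minimum count 10, minimum total 15), counts were scaled with TMM factors, and the age term was tested two-sided with the quasi-likelihood F-test of edgeR, adjusted by Benjamini-Hochberg at a threshold of 0.05. CPM values use the TMM-scaled library sizes. The standard error of a log2 change was taken as its size divided by the square root of its F statistic. The 29 gene lists, the rule for naming genes, the tests and all alternatives but 2 were written down before the data were examined. Of the lists, 28 had at least 5 tested genes and were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists. Shares of counts in gene classes were compared by exact permutation, which cannot give a two-sided p below 0.333 with 2 libraries against 2. Principal components and correlations used log2 CPM with a prior count of 2.

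The naming rule picks Itgb3, Tet2, Tnf, Ccr2, Ly6c2 and Csf1r in any case. To these come the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out unnamed models and pseudogenes. From each list with members past the threshold come up to 4 per direction with the smallest p, and from a list without any, the member with the smallest p. From the lists of other cell types and of quality come also the 2 most abundant members, per library. Genes outside this rule are said to be so where they appear.

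Alternatives were RLE, upper-quartile and library-size scaling, library sizes without the 20 most abundant genes, 3 other low-count filters, DESeq2, limma-voom, robust edgeR, a 2-fold limit, glmTreat against 1.2-fold, the replicate number as a block, and each library left out in turn. List tests were repeated with an estimated correlation, with fry and on limma-voom values. Chosen after seeing the data were per-library GC content and length trends as offsets (natural splines with 5 degrees of freedom) and the removal of immunoglobulin genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

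The procedure was tested on simulated data with 2 libraries per group, in which 11887 genes entered the edgeR test. It recovered 10 of 50 genes changed by 1.25-fold, 33 of 50 at 1.5-fold, 42 of 50 at 2-fold and 50 of 50 at 4-fold, with 5 calls among unchanged genes. In the same simulation, which drew each gene independently, camera called the 1 list that had been moved, by 1.25-fold (adjusted p = 3.15e-12), and 0 of 27 unmoved lists. It therefore does not measure the false calls that correlated genes would give. With an estimated correlation the moved list gave an adjusted p = 0.385, and with fry an adjusted p = 0.0793.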

Results

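The series measured gene expression in sorted bone marrow monocytes of aged (18 months) and young (3 months) mice, with 2 libraries per age. Its title places the comparison in a study of how the age of the bone marrow affects the clonality of smooth muscle-derived cells in atherosclerotic plaques. Library totals ranged from 20159129 to 34278754 counts, and 12035 genes were tested. Lyz2, the lysozyme gene of myeloid cells, was the most abundant gene in all 4 libraries, with 3.30% to 3.51% of the counts. All 4 libraries came from male cells by their transcripts, with 0 counts of Xist and between 1006 and 1799 counts of the Y-linked Eif2s3y. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Genome positions are on GRCm38, and errors of log2 changes are standard errors with n = 2 per group.

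Aged and young monocytes differed in 694 genes, of which 346 were higher and 348 lower in the aged libraries. The size of most changes was modest, with a median of 0.46 on the log2 scale, and 92 genes rose and 24 fell by at least 2-fold. Leaving aside immunoglobulin genes, the largest rises among genes of at least 5 CPM were those of Cd300e, an activating receptor of myeloid cells (log2 change 2.44 ± 0.25), the immediate early transcription factors Egr1 (2.14 ± 0.11) and Fos (3.99-fold), Cd36, a scavenger receptor for oxidised lipoproteins (1.86 ± 0.11), Gpnmb (1.82 ± 0.13) and the carboxylesterase Ces1d (1.74 ± 0.16). The largest falls at that level, outside immunoglobulin genes and unnamed gene models, were those of mt-Nd5 (-1.30 ± 0.061), Hist1h2ae (-1.27 ± 0.29) and Neto2 (-1.04 ± 0.19). The first principal component held 58.7% of the variance and separated the ages. Log2 CPM correlated across genes at 0.990 between the aged libraries and 0.991 between the young ones, against 0.981 to 0.983 across ages. Groups did not overlap in any of the 694 genes, and over all tested genes in 51.6%, where chance gives 33.3%. Without young replicate 1, the deepest library, 197 genes passed (116 higher, 81 lower), without young replicate 2 the genes higher in aged numbered 216, and without aged replicate 1 the lower ones 588. Hist1h2ae and Neto2 did not pass without young replicate 1 (adjusted p = 0.157 and 0.0725), and Hist1h2ae also not without aged replicate 2 (0.077). The fall of Hist1h2ae ranged from -1.73 to -0.57 over the libraries left out, with 106 and 47.6 CPM in the young libraries.

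**Figure D1:**
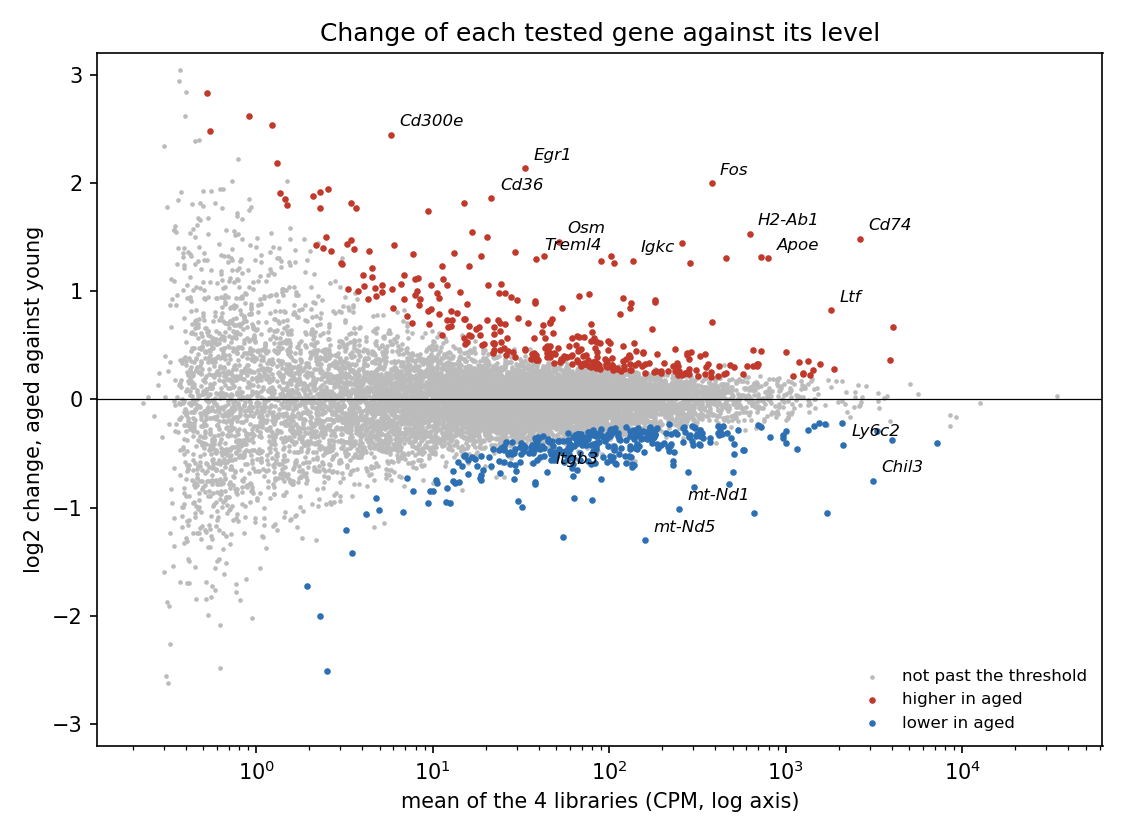
Log2 change of aged against young monocytes (vertical axis) against the mean of the 4 libraries in CPM (horizontal log axis), 1 point per tested gene, with 346 genes higher (red) and 348 lower (blue) in aged libraries. The 33 genes beyond 3.2 on either side are not drawn, and Cd74, Fos and mt-Nd5 stand apart from genes of similar level.

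Itgb3, the integrin beta-3 chain, fell from 54.8 ± 5.58 CPM in young to 34.2 ± 1.49 CPM in aged monocytes (SD, n = 2 per group), a log2 change of -0.68 ± 0.099 (edgeR adjusted p = 0.00346; chromosome 11, 104608000 to 104670476). Ly6c2, the marker of classical monocytes, fell from 2413 ± 107 to 1804 ± 13.2 CPM (-0.42 ± 0.052, adjusted p = 0.00118; chromosome 15, 75108158 to 75111970). Csf1r, the receptor for macrophage colony-stimulating factor, rose from 1388 ± 6.21 to 1739 ± 40.3 CPM (0.33 ± 0.049, adjusted p = 0.00429; chromosome 18, 61100598 to 61132149). These 3 genes also passed with each library left out. The DNA demethylase gene Tet2 stood at 42.3 ± 4.34 CPM in aged and 50.3 ± 6.24 CPM in young monocytes (-0.25 ± 0.11, adjusted p = 0.221; chromosome 3, 133463679 to 133545139), a difference that did not pass in the main test. With the replicate number as a block Tet2 passed, as given with the alternatives below. Tnf was low, at 6.35 ± 1.37 against 4.23 ± 0.124 CPM (0.59 ± 0.22, adjusted p = 0.163; chromosome 17, 35199381 to 35202007), and passed in 1 alternative, without aged replicate 1 (0.045). Ccr2, the receptor that draws monocytes out of the marrow, gave 0.17 ± 0.064 (adjusted p = 0.155; chromosome 9, 124101950 to 124113557). It passed without aged replicate 2 (0.0231), with no low-count filter (0.00457) and with offsets for GC content and length (0.0219).

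Genes of MHC class II antigen presentation rose together in aged monocytes. Of 10 tested members 7 rose, 8 when adjusted over the list alone, and the median log2 change was 1.10. Cd74, the invariant chain, rose from 1383 ± 53.6 to 3868 ± 169 CPM (SD, n = 2 per group), a log2 change of 1.48 ± 0.055 (adjusted p = 2.33e-07; chromosome 18, 60803848 to 60812652). The class II chains H2-Ab1 (1.53 ± 0.057; chromosome 17, 34257689 to 34269419), H2-Aa (1.31 ± 0.059) and H2-Eb1 (1.44 ± 0.081) rose by similar amounts. Genes of non-classical monocytes, the patrolling subset, rose as well, 12 of 19 members over all genes and 14 adjusted over the list alone, with a median of 0.93. Among them were Cd36, Adgre4 (0.92 ± 0.060), Nr4a1, the transcription factor that this subset depends on (1.26 ± 0.083), and Treml4 (1.30 ± 0.090). Nr4a1 is also held by the immediate early list described below. Outside the naming rule, the abundant Cx3cr1 (0.32 ± 0.16, edgeR adjusted p = 0.283), Itgal (0.089 ± 0.053, 0.37) and Myo1g (0.019 ± 0.054, 0.883) did not pass. Neither did Spn, whose sign was negative (-0.24 ± 0.12, 0.27). Genes of classical monocytes moved opposite to the non-classical list, with 5 of 14 members lower and 1 higher, 10 and 2 adjusted over the list alone, and a median of -0.24. Chil3 fell most surely, from 3920 ± 43.5 to 2327 ± 33.5 CPM (-0.75 ± 0.048; chromosome 3, 106147554 to 106167564), along with Ly6c2 and Ccl9 (-0.34 ± 0.060), while Tmem176a rose (0.95 ± 0.077). Of 18 monocyte identity genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 0.040; Spi1 rose by 0.30 ± 0.053 and Cd68 by 0.25 ± 0.052, and Mpeg1 fell (-0.25 ± 0.059). In camera the adjusted p was 4.9e-52 for MHC class II, 9.25e-34 for the non-classical list, 0.000621 for the classical list and 0.0043 for monocyte identity. With an estimated correlation the adjusted p was 0.0984 for MHC class II and the non-classical list and 0.184 for the classical and identity lists. Without aged replicate 2 the identity list gave an adjusted p = 0.0671. Without young replicate 1, Ccl9 (0.0925) and Spi1 (0.0751) did not pass; Mpeg1 was lost without it (0.234) or aged replicate 2 (0.115), and Cd68 without either of these (0.185 and 0.063) or young replicate 2 (0.0736).

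Some markers of B cells and of dendritic cells rose too. Of 17 B-lineage genes 7 rose, 11 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 1.1e-12; adjusted p = 0.108 with an estimated correlation). Its most abundant members were Ighm, at 841 and 838 CPM in the aged and 608 and 622 CPM in the young libraries, and Igkc, at 193 and 191 against 80.7 and 77.6 CPM. Ighd (1.37 ± 0.27) and Cd79b (0.51 ± 0.11) rose too, but Ighd was lost without aged replicate 2 (0.062) or young replicate 1 (0.108), and Cd79b without any library other than aged replicate 1 (0.0755 to 0.154). Of 18 dendritic cell genes 4 rose, 5 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.013; adjusted p = 0.196 with an estimated correlation). They were Spib (0.81 ± 0.15), Flt3 (0.47 ± 0.095), Itgax (0.66 ± 0.14) and Clec10a (0.37 ± 0.093), and none of the 4 passed without young replicate 1 (adjusted p = 0.05 to 0.268). The abundant Cd209a stood at 138 and 140 CPM in the aged and 125 and 131 CPM in the young libraries, and Tcf4 at 54.0 and 55.5 against 50.6 and 47.8 CPM. The dendritic cell list itself did not pass without aged replicate 2 (0.0517) or young replicate 2 (0.0637).

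**Figure D2:**
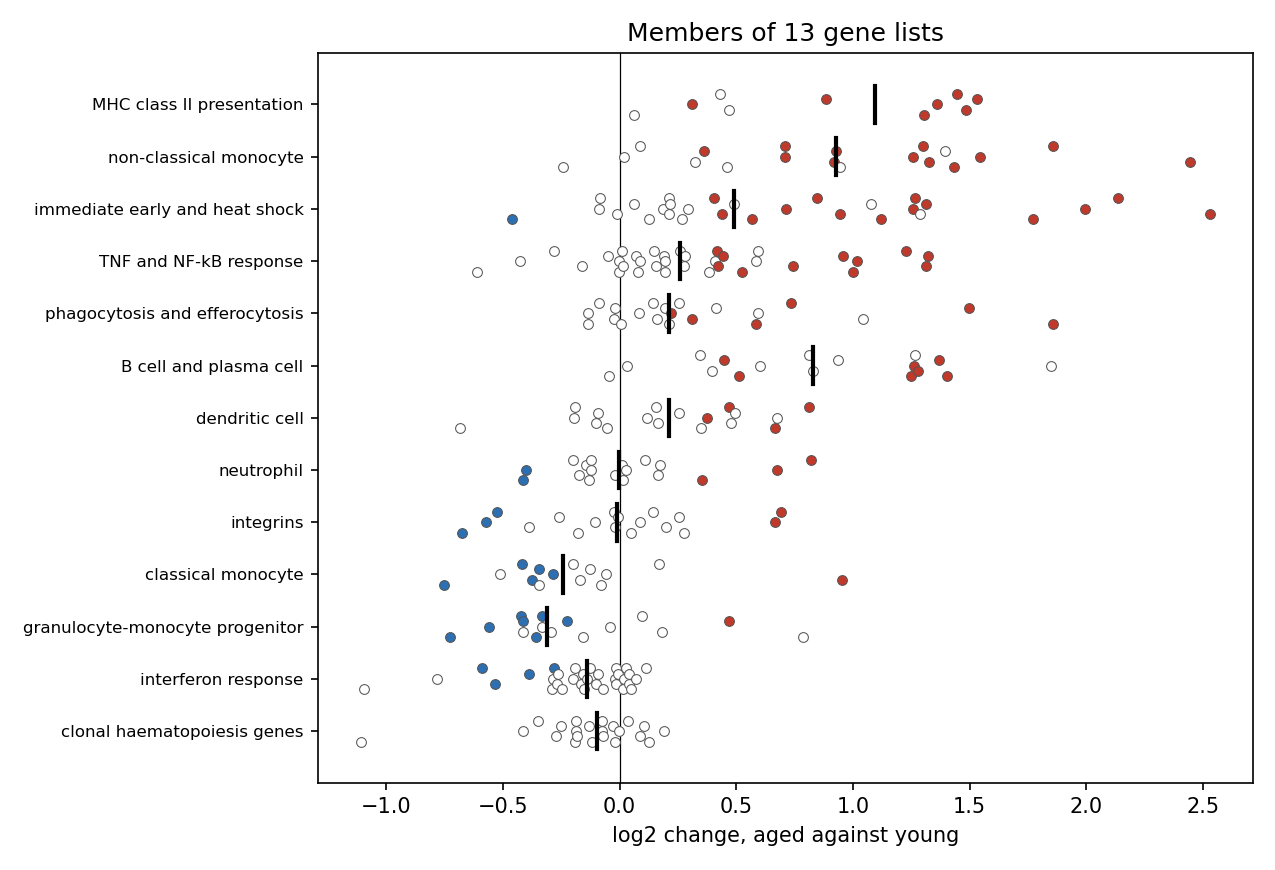
Log2 change of aged against young monocytes for the tested members of 13 gene lists; filled points passed an edgeR adjusted p of 0.05 (red higher, blue lower), open points did not, and the black bar is the list median. Medians run from 1.10 for MHC class II presentation to -0.31 for granulocyte-monocyte progenitor genes.

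Immediate early and stress genes were higher in aged monocytes. In a list fixed as a sign of sample quality, 14 of 29 members rose and 1 fell, 20 and 1 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 2.01e-41; adjusted p = 0.0984 with an estimated correlation). Fos rose from 153 ± 9.84 to 609 ± 15.1 CPM (SD, n = 2 per group; chromosome 12, 85473890 to 85477273), Egr1 from 12.3 ± 1.30 to 54.5 ± 2.26 CPM, and Dusp1, a phosphatase that ends MAP kinase signalling, by 1.26 ± 0.056 on the log2 scale. Zfp36, which destabilises inflammatory messenger RNAs, stood at 998 and 1062 CPM in the aged and 413 and 415 CPM in the young libraries (1.31 ± 0.055), and the chaperone gene Hspa8 at 1143 and 1160 against 828 and 871 CPM. Fosl2 fell (-0.46 ± 0.11) but was lost without young replicate 1 (0.111) or young replicate 2 (0.0865). Genes of the TNF and NF-kB response rose too, 11 of 35, with 17 higher and 2 lower adjusted over the list alone and a median of 0.26 (camera adjusted p = 5.19e-10; adjusted p = 0.113 with an estimated correlation). Among these 11, next to Zfp36, which both lists hold, were the chemokine genes Ccl3 (1.32 ± 0.13) and Cxcl2 (1.23 ± 0.14) and the NF-kB subunit gene Nfkb2 (0.52 ± 0.071). The other 24 did not pass. Among these, outside the naming rule, were Nfkbia (0.012 ± 0.073, edgeR adjusted p = 0.946), Il1b (-0.16 ± 0.092, 0.349) and Rel (-0.43 ± 0.11, 0.0554).

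Among 21 chemokine and chemokine receptor genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone, with a median of 0.39. Besides Ccl3 and Cxcl2, Ccrl2 (0.98 ± 0.16) and Cxcl16 (1.15 ± 0.23) rose, and the falls were those of Cxcr2 (-0.42 ± 0.061), Ccl9 and Cxcr4, the receptor that holds cells in the marrow (-0.58 ± 0.13). Of 14 tested genes for ligands that act on smooth muscle cells, the cytokine gene Osm rose from 27.9 ± 2.84 to 76.4 ± 7.03 CPM (1.46 ± 0.10; chromosome 11, 4236420 to 4241026), C3 fell from 1342 ± 13.4 to 974 ± 78.2 CPM (-0.46 ± 0.061) and Thbs1 fell (-0.36 ± 0.077); the count was the same adjusted over the list alone, 1 higher and 2 lower, and the median was 0.033. The camera adjusted p was 0.00531 for chemokines and 0.441 for the ligands, and with an estimated correlation the adjusted p was 0.224 for chemokines. The chemokine list did not pass without aged replicate 1 (0.0603) or with genes of at least 5 CPM alone (0.224). Cxcl16 was lost without young replicate 1 (0.0936) or young replicate 2 (0.0671), Cxcr4 and Ccl9 without young replicate 1 (0.0928 and 0.0925), and Thbs1 without any library other than aged replicate 1 (0.0721 to 0.162).

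Genes of lipid handling and of the uptake of dying cells rose in part. Apoe, the apolipoprotein that carries cholesterol out of macrophages, rose from 458 ± 7.72 to 1133 ± 37.9 CPM (SD, n = 2 per group), a log2 change of 1.31 ± 0.054 (chromosome 7, 19696109 to 19699188). The phospholipid transfer protein gene Pltp (1.32 ± 0.088), Cd36 and the fatty acid carrier gene Fabp4 (1.43 ± 0.26) rose, and the lipid droplet gene Plin2 fell (-0.26 ± 0.058). These were the 5 changed genes of 23 in the cholesterol efflux list, 6 higher and 2 lower adjusted over the list alone, with a median of 0.069 (camera adjusted p = 3.9e-05; adjusted p = 0.188 with an estimated correlation). On limma-voom values this list gave an adjusted p = 0.0517, and without aged replicate 2 its median was -0.015. Of 21 phagocytosis and efferocytosis genes 6 rose, 7 adjusted over the list alone, with a median of 0.21, among them Cd36, the complement genes C1qb (from 10.7 ± 0.192 to 30.2 ± 0.0955 CPM) and C1qc (0.73 ± 0.14) and the receptor gene Axl (0.59 ± 0.082); the camera adjusted p was 4.23e-08, and the adjusted p = 0.113 with an estimated correlation. C1qb, C1qc and Axl were also the 3 of 13 marrow macrophage genes that rose, 3 higher and 1 lower adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00456; adjusted p = 0.196 with an estimated correlation). The most abundant macrophage genes were Slc40a1, at 192 and 171 CPM in the aged and 210 and 236 CPM in the young libraries, and Hmox1, at 109 and 116 against 103 and 106 CPM. Without young replicate 1, Fabp4 (0.061) and C1qc (0.117) did not pass, and Plin2 was lost without any library other than aged replicate 2 (0.0576 to 0.186).

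Integrin genes changed in both directions. Itgb5 rose by 0.69 ± 0.072 and Itgax by 0.66 ± 0.14, while Itgb3, Itga1 (-0.53 ± 0.085) and Itga4, the alpha chain of the receptor for VCAM-1 (-0.57 ± 0.11), fell. The other 13 of 18 tested members did not pass, 4 were higher and 5 lower adjusted over the list alone, the median was -0.013 and the camera adjusted p 0.671. Itgax, Itga1 and Itga4 did not pass without young replicate 1 (0.196, 0.0541 and 0.0848). None of 22 clonal haematopoiesis and DNA methylation genes passed with edgeR, DESeq2 or limma-voom, or adjusted over the list alone, although 8 had an unadjusted edgeR p under 0.05. Their median was -0.097, the camera adjusted p 0.0813 (0.253 with an estimated correlation), and the smallest p belonged to Dnmt1 (-0.19 ± 0.062, adjusted p = 0.106). That list passed, as lower in aged monocytes, with fry (0.0196), with camera on limma-voom values (0.0373) and with camera under the replicate number as a block (0.0449). Without aged replicate 1 its median was -0.12. Of 15 senescence genes Mmp14 (1.92 ± 0.32), Cxcl16 and Plaur (0.25 ± 0.062) rose and the lamin gene Lmnb1 fell (-0.49 ± 0.073), 4 higher and 1 lower adjusted over the list alone, with a median of 0.12 and a camera adjusted p of 0.174. Mmp14 was lost without young replicate 1 (0.05), and Plaur without any library other than aged replicate 1 (0.0889 to 0.309). The counts of Cdkn2a, the p16 gene, were 3 and 0 in the aged and 3 and 2 in the young libraries, too few to compare.

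Interferon response genes were lower in aged monocytes in 4 of 33 cases, 6 adjusted over the list alone, with a median of -0.14. Ifi27l2a fell from 158 ± 8.92 to 109 ± 1.93 CPM (SD, n = 2 per group; log2 change -0.53 ± 0.068), and Slfn1 (-0.28 ± 0.057), Oas3 (-0.59 ± 0.12) and Rsad2 (-0.39 ± 0.083) fell as well. Of 35 cell cycle genes Mcm7, a subunit of the replicative helicase, fell (-0.30 ± 0.063), 5 were lower adjusted over the list alone, and the median was -0.14. Of 40 oxidative phosphorylation genes encoded in the nucleus Cox7a2 (-0.33 ± 0.073), Cox7b (-0.37 ± 0.086) and Ndufa4 (-0.34 ± 0.079) fell, the same 3 in number adjusted over the list alone, with a median of -0.10. The camera adjusted p was 0.00171 for interferon, 0.000621 for cell cycle and 0.00499 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.184, 0.184 and 0.253 in that order. No member passed with edgeR among 24 cholesterol biosynthesis genes (median 0.015, camera adjusted p = 0.789) or 25 glycolysis and hypoxia genes (median 0.017, camera adjusted p = 0.597), or adjusted over each list alone; 1 and 4 had an unadjusted p under 0.05, and DESeq2 called 0 of each and limma-voom 0 and 1. Their smallest p values were those of Msmo1 (0.23 ± 0.075, adjusted p = 0.106) and Eno1 (0.18 ± 0.054, adjusted p = 0.083). Of the genes that fell here, Ifi27l2a passed with each library left out, whereas the others were lost without young replicate 1 (adjusted p = 0.0751 to 0.294) and, except Oas3, without another library too.

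Mitochondrially encoded and histone genes made up most of the other large falls. Oligo-dT selection leaves out most transcripts without a poly(A) tail. A difference in that selection between the groups was not tested and cannot be told apart from a fall of histone transcripts in the cells. mt-Nd5, a subunit of respiratory complex I, fell from 226 ± 0.560 to 91.8 ± 0.839 CPM (SD, n = 2 per group; mitochondrial genome, 11742 to 13565), and mt-Nd1 (-1.01 ± 0.076), mt-Nd6 (-0.94 ± 0.10) and mt-Nd2 (-0.93 ± 0.11) fell with it. Mitochondrial genes held 0.106% and 0.0893% of the counts in the aged and 0.174% and 0.188% in the young libraries, with 7 of 11 tested genes lower. The exact binomial 95% intervals of these shares were 0.105% to 0.107%, 0.0881% to 0.0906%, 0.172% to 0.175% and 0.186% to 0.190%. Hist1h1b (-0.99 ± 0.15), Hist1h2ac (-0.96 ± 0.19) and Hist1h4d (-0.91 ± 0.14) fell, and 9 of 54 histone genes did so, but their share was 0.358% ± 0.000685 in aged and 0.384% ± 0.0231 in young libraries. Ribosomal protein genes fell in 49 of 81 cases, with a median of -0.33 and a share of 1.17% ± 0.0139 against 1.46% ± 0.114. Haemoglobin genes held 0.0352% ± 0.000104 against 0.0343% ± 0.00323 and the 20 most abundant genes 13.1% ± 0.173 against 13.6% ± 0.831. Immunoglobulin genes held 0.123% ± 0.00114 against 0.0770% ± 0.000596. The exact permutation p of the shares was 0.333 for mitochondrial, ribosomal protein, immunoglobulin and histone genes, the smallest this design can give, and 1 for haemoglobin and the top 20 genes. The remaining large falls were Sema4b (-0.95 ± 0.14) and Ypel2 (-0.96 ± 0.22), which like Hist1h2ac did not pass without young replicate 1 (0.05, 0.206 and 0.176).

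Immunoglobulin V and C genes showed the most extreme differences, in both directions. Igkv15-103 had 643 and 522 counts in the aged libraries and 0 in both young ones, at least 210-fold higher against a floor of 3 counts per library (chromosome 6, 68437440 to 68437925). Igha, the constant region of IgA, had 556 and 536 counts against 0 and 1 (chromosome 12, 113254830 to 113260236), a ratio with a counting interval from 228 to 50264. Igkv12-89 (325 and 270 against 1 and 0), Igkv5-48 (346 and 350 against 1 and 1), Igkv4-55 (422 and 442 against 1 and 3) and Ighv7-1 (376 and 329 against 1 and 3) were also nearly limited to aged libraries. Igkv14-126 went the other way, with 18 and 6 counts in the aged and 941 and 576 in the young libraries, 56.2-fold higher in young (chromosome 6, 67896172 to 67896642). All 7 genes passed in edgeR (adjusted p from 2.33e-07 to 6.79e-07), and 20 immunoglobulin genes were higher and 8 lower in total.

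**Figure D3:**
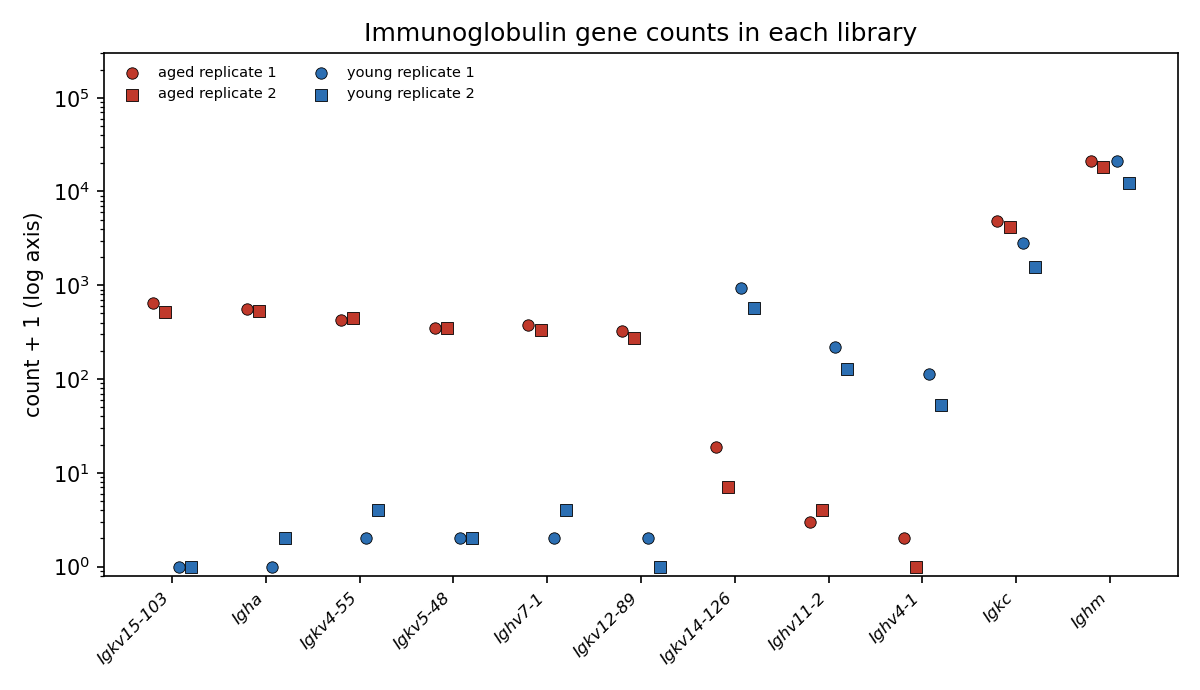
Counts plus 1 (vertical log axis) of 11 immunoglobulin genes in each library, aged in red and young in blue, replicate 1 as circles and replicate 2 as squares. Igkv15-103 has 643 and 522 counts in aged and 0 in young libraries, and Igkv14-126 18 and 6 against 941 and 576.

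Transcripts of granulocyte precursors and neutrophils were present in all libraries of these sorted cells. Granulocyte-monocyte progenitor genes were lower in aged libraries, with 7 of 16 lower and 1 higher, 9 and 1 adjusted over the list alone, and a median of -0.31 (camera adjusted p = 0.000621; adjusted p = 0.184 with an estimated correlation). Ms4a3 (-0.56 ± 0.080), Cd93 (-0.42 ± 0.074) and the granule protease genes Prtn3 (-0.36 ± 0.064) and Elane fell, and Flt3 rose. Mpo, the myeloperoxidase gene, stood at 1527 and 1547 CPM in the aged and 1741 and 1854 CPM in the young libraries, and Elane at 840 and 869 against 1064 and 1086 CPM. The neutrophil list split, with 3 of 18 higher and 2 lower, 4 and 4 adjusted over the list alone, a median of -0.0048, a mean of 0.034 and a camera adjusted p of 0.271 in the higher direction. Ltf (0.82 ± 0.051), Ngp (0.67 ± 0.049) and Cd177 (0.35 ± 0.053) rose, whereas S100a8 (-0.40 ± 0.054) and Cxcr2 fell. S100a8 stood at 6078 and 6357 CPM in the aged and 8551 and 7885 CPM in the young libraries, and S100a9 at 7929 and 8385 against 9193 and 8832 CPM. Without young replicate 1, Prtn3 (0.116), Cd93 (0.0522), Flt3 (0.178) and Mpo (0.0611) did not pass; Cd93 was lost also without young replicate 2 (0.0531), and Mpo without it (0.143) or aged replicate 2 (0.0516).

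Other cell types contributed few counts. Of 15 erythroid genes Car2 (1.23 ± 0.16) and Slc4a1 (1.34 ± 0.22) rose, 8 were higher and 1 lower adjusted over the list alone, with a median of 1.23 (camera adjusted p = 4.83e-05; adjusted p = 0.184 with an estimated correlation), and Slc4a1 was lost without young replicate 1 (0.0603). The haemoglobin genes Hbb-bs, at 160 and 162 CPM in the aged and 178 and 158 CPM in the young libraries, and Hba-a1, at 113 and 117 against 108 and 101 CPM, did not pass. Of 15 eosinophil, basophil and mast cell genes Prg2 and Epx (0.68 ± 0.16) rose, 2 higher and 1 lower adjusted over the list alone; the median was -0.070, the mean 0.030 and the camera adjusted p 0.966 in the lower direction. Prg2 stood at 75.7 and 71.3 CPM in aged and 56.1 and 58.2 CPM in young libraries, and Hdc at 178 and 166 against 174 and 182 CPM; Prg2 and Epx were lost without young replicate 1 (0.205 and 0.287), Prg2 also without young replicate 2 (0.0715) and Epx without aged replicate 2 (0.0754). Among 6 stromal and endothelial genes Acta2 fell (-0.58 ± 0.10), with 25.7 and 24.4 against 39.0 and 35.7 CPM, and Pecam1 stood at 14.2 and 14.4 against 16.9 and 18.4 CPM; 2 were higher and 1 lower adjusted over the list alone, the median was 0.13, the mean 0.48 and the camera adjusted p 0.966 in the lower direction. Acta2 was lost without young replicate 1 (0.0971).

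T and NK cell transcripts were low, with Il2rb at 7.10 and 8.88 CPM in the aged and 9.61 and 9.43 CPM in the young libraries, and Cd3d at 3.15 and 4.69 against 3.68 and 3.96 CPM. None of the 18 genes passed with edgeR, DESeq2 or limma-voom, or adjusted over the list alone, 1 had an unadjusted p under 0.05 (Cd4, 1.24 ± 0.39, adjusted p = 0.0955), the median was 0.27 and the camera adjusted p 0.235. Of 6 megakaryocyte and platelet genes none passed with the same 3 tools, 3 had an unadjusted p under 0.05 and 2 were higher adjusted over the list alone. Pf4 gave 1.56 ± 0.54 (adjusted p = 0.127), Itga2b lay between 0.753 and 1.33 CPM in the 4 libraries, and Vwf stood at 0.838 and 1.33 CPM in the aged and 0.753 and 0.903 CPM in the young ones. That list had a median of 1.18 (camera adjusted p = 0.0128; adjusted p = 0.209 with an estimated correlation) and did not pass without aged replicate 1 (0.0894). Among the 4 tested sex-linked genes none passed with edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05, Ddx3y, at 66.9 and 61.1 CPM in the aged and 53.4 and 57.9 CPM in the young libraries (adjusted p = 0.206), while Eif2s3y stood at 49.8 and 49.9 against 52.1 and 50.5 CPM. The list has under 5 tested genes and its median of -0.087 was not tested.

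In total camera placed 18 of 28 lists past the threshold, 13 higher and 5 lower in aged monocytes. With an estimated correlation it placed 0 there, with 6 at an unadjusted p under 0.05, and fry called 14. Of the 18 lists fry did not call those of classical monocytes, monocyte identity, dendritic cells and megakaryocytes (adjusted p = 0.052 each) and of oxidative phosphorylation (0.0598). A moved list in simulated libraries of this design was also missed with an estimated correlation (adjusted p = 0.385).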

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

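The GC content and length offsets and the removal of immunoglobulin genes were chosen after the result was seen. The 694 changed genes became 634 to 699 under the 4 other scalings, 668 to 704 with the CPM filters, and 682 to 809 with DESeq2, limma-voom and robust edgeR. The median log2 change of all genes lay between -0.0046 and 0.0083 under these scalings, and the medians of ribosomal protein, mitochondrial and histone genes stayed negative. Library sizes without the 20 most abundant genes gave the same 694. TMM factors were computed again on those sizes, so that scaling is no separate check. Under every alternative each of the 694 genes that was still tested kept its sign. With a library left out this was nearly fixed in advance, since the groups did not overlap in any of the 694. The offsets gave 834 changed genes, 604 of them among the 694, and without immunoglobulin genes 645 changed. Larger moves came with no low-count filter (1399 changed, 606 higher and 793 lower; the cause was not tested) and, by construction, with at least 2-fold change (116, 92 and 24) and glmTreat (161, 110 and 51).

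With 1 library left out, the count ran from 197 to 1040, the genes higher in aged from 116 to 452 and those lower from 81 to 588, the lone library being assumed to vary like the pair of the other age. Of 99 genes past the threshold that the naming rule picks, not all of which are printed, 41 were lost without young replicate 1, 14 each without aged replicate 2 or young replicate 2, and 1 without aged replicate 1. Changes of sign occurred in named genes that had not passed: Cd3d ranged from -0.27 to 0.30, Hbb-bs from -0.15 to 0.025 and Itga2b from -0.013 to 0.74. Among lists that had not passed, camera's direction turned for smooth muscle ligands (adjusted p from 0.0601 to 0.691 over the libraries left out), eosinophils, basophils and mast cells (0.695 to 0.802) and stromal and endothelial genes (0.651 to 0.987). With an estimated correlation 0 lists passed, and fry placed 14. The estimated correlation was -0.028 for MHC class II, -0.028 for the B cell list and 0.0071 for the TNF list. These lie below the preset 0.01, which argues against a correlation above the preset as the reason why these lists were lost. Other lists lay above it, such as non-classical monocytes (0.047) and immediate early genes (0.057). What else differs between these list tests was not tested.

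The replicate number as a block gave 1817 changed genes (801 higher, 1016 lower) and let Tet2 (adjusted p = 0.0442) and the clonal haematopoiesis list (0.0449) pass. Deviations of same-numbered libraries correlated at 0.094 across genes, and the labels give no shared litter or day, so the numbers were not taken to pair the libraries. Single genes, picked after their values were seen, did split by number in both ages. Supt16 stood at 53.3 and 21.2 CPM in the aged and 56.2 and 25.5 CPM in the young libraries. Hist1h1e stood at 119 and 58.3 against 162 and 73.5 CPM. Lars2 did not split so, and whether the numbers carry a meaning stays open. The simulation limits what depth and 2 libraries per group can show, with 10 of 50 genes of its smallest change recovered.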

Other observations

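The genes of these first paragraphs were chosen after their values were seen, and all tests of the patterns that follow were chosen after the result was seen. Among 5 class I genes looked at beyond class II, which form no fixed list, H2-D1 rose from 3404 ± 202 to 4376 ± 96.9 CPM (SD, n = 2 per group; log2 change 0.36 ± 0.054), while B2m, the light chain (-0.074 ± 0.052, adjusted p = 0.458), and H2-K1 (0.20 ± 0.057, adjusted p = 0.0709) did not pass. H2-Q6 (0.94 ± 0.15, adjusted p = 0.00568) and H2-Q7 (0.68 ± 0.12, adjusted p = 0.0106) passed with all libraries but not without young replicate 1 (0.0603 and 0.0541). Single genes that about doubled, picked one by one and forming no fixed list, were S1pr5, a sphingosine phosphate receptor (0.98 ± 0.11), Tmem176b (0.90 ± 0.060), Aif1 (0.89 ± 0.092) and Slamf7 (0.98 ± 0.13). Olfm4, a gene of a neutrophil subset, rose from 52.3 ± 4.45 to 127 ± 0.193 CPM. Notch1 (-0.60 ± 0.073) and Notch2 (-0.67 ± 0.081), with 14232 and 10782 exonic bp, fell. Apart from H2-Q6 and H2-Q7, all of these calls held with each library left out. Falls outnumbered rises among the longest genes, as given below, and whether length bears on Notch1 and Notch2 was not examined.

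Of 7 genes known to be induced by glucocorticoids, which form no fixed list and were not tested as a set, 2 fell in aged monocytes also with each library left out: Tsc22d3 from 279 ± 3.87 to 183 ± 4.08 CPM (SD, n = 2 per group) and Txnip from 667 ± 8.09 to 483 ± 12.5 CPM. Per1 (-0.76 ± 0.18, adjusted p = 0.0388) and Fkbp5 (-0.41 ± 0.096, adjusted p = 0.0358) passed with all libraries, but Per1 did not without any library other than aged replicate 2 (0.0603 to 0.14) and Fkbp5 not without any other than aged replicate 1 (0.112 to 0.148). Klf9 (adjusted p = 0.273), Ddit4 (0.163) and Zbtb16 (0.807) did not pass. Gm42418, which overlaps ribosomal RNA sequence, fell from 888 ± 10.7 to 430 ± 13.5 CPM. The ribosomal RNA-like Gm26917 fell from 2307 ± 563 to 1111 ± 538 CPM (edgeR adjusted p = 0.0415), and Lars2 did not pass (0.229). Whether oligo-dT selection differed between the groups was not tested for these genes either. Among the 1191 longest genes by exonic length 84 were lower and 12 higher, against 61 and 44 among the 1191 shortest, and the median log2 change was negative in both (-0.096 and -0.052). Libraries of an age differed here: the rank correlation of a library's deviation from the mean of all 4 with length was -0.0065 and -0.16 in aged replicates 1 and 2 and 0.066 and 0.11 in young replicates 1 and 2. With GC content it was -0.086 and 0.26 in the aged and -0.085 and -0.091 in the young libraries, aged replicate 2 standing apart.

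Both libraries of an age group carried the same immunoglobulin V genes. Ighv11-2, which with Igkv14-126 forms a known antibody of B-1 cells, had 219 and 126 counts in the young and 2 and 3 in the aged libraries. The V gene profiles differed by a chi-square per degree of freedom of 1.60 between the aged and 2.39 between the young libraries, against 83.9 to 99.0 across ages, which measures the pattern and does not decide its cause. B-lineage cells of the same animals or pool in both libraries of an age and V gene use that all mice of an age share cannot be told apart, since 0 columns of the labels tie a library to an animal. The labels give the same strain for both ages.

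MHC class II genes were higher in aged libraries, and a different mixture of cells may contribute. If another cell type were the whole source, transcripts that it alone expresses would have to rise at least as much as Cd74. The bar is a log2 change of 1.37, after taking off 2 standard errors of Cd74. Members of at least 5 CPM count as reaching it if their own change plus 2 standard errors does. Among dendritic cell genes 0% of 11 such members, and 1 of all 18 tested, reached it. This does not decide whether dendritic cells were the whole source. A member that other cells here express too, such as Flt3 of the progenitor list, would rise less. Among B-lineage genes 16.7% of 6 reached it (Igkc alone), with Ighm at 0.45 ± 0.051 and Cd79b at 0.51 ± 0.11. Of all 17 tested, 10 reached it, so the members split and do not decide whether B cells were the whole source. The 14 B-lineage genes other than immunoglobulin genes together rose by 29.9 CPM and Cd74 by 2485 CPM. The same sum was 47.0 CPM for dendritic cell genes and 539 CPM for non-classical monocyte genes. All 3 sums lie below the rise of Cd74, so they do not separate these sources. Of non-classical monocyte genes 40% reached the bar (6 of 15). A larger share of these cells therefore cannot be told apart from a change within classical monocytes, both being monocytes of the same sort. Nr4a1, among these 6, is also held by the immediate early list. A change with age inside each cell stays open, untested.

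Immediate early genes were higher in aged libraries, with a list median of 0.49 on the log2 scale. A GC content and length trend between libraries is argued against, since the median was 0.47 and 14 members were higher with offsets for both. Handling of the aged cells between marrow and lysis may also induce these genes, and it cannot be told apart from age, because each age is 1 group and the labels give no day or order of handling. Induction within the marrow of aged mice stays open, untested.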
